A study of Mus musculus with 4 samples.

How the data were processed

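Gene expression was measured with 1-colour Affymetrix arrays in hair follicles that had been cut out of dorsal skin sections by laser capture microdissection, a method in which a laser frees chosen structures from a section on a slide. Per the labels' protocols, frozen skin was sectioned at 8 micrometres and stained, 50 to 70 follicles were pooled per sample, and RNA was amplified before a biotin-labelled cRNA was made from it. The labels do not say which part of the follicle was outlined. The deposited values are linear probe set intensities. From the values, each array had been scaled by the authors to a common level, since the mean without the lowest and highest 2% of probe sets was 165 on all 4 arrays. The software that made the intensities, its version and the background correction are not given in the sources used here. No read depth exists for arrays, and the small number of arrays limits the precision.

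Samples were grouped by strain field, title and the design text into 2 heterozygous samples (replicates 3 and 4) and 2 homozygous samples (replicates 2 and 3). The titles and source names of the heterozygous samples carry the prefix WT, and their genotype comes from the strain field and from the design text, which names heterozygotes as the controls. For homozygous replicate 3 the labels conflict: its title and source name carry the prefix of the homozygous samples, its source name has the number of the other homozygous sample, and its strain field gives the heterozygous genotype. It was kept with the homozygous group, and grouping by the strain field was run as an alternative. That grouping leaves homozygous replicate 2 as the only homozygous sample, assumed to vary like the others. The labels name littermates but do not tie each array to an animal, so limma p-values of probe sets measure the spread between these samples, which may be technical. Camera p-values with the preset correlation compare the statistics of a list's members with those of other genes. They do not measure how a list varies between samples. No batch is given in the labels.

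Intensities were transformed to log2(intensity + 32), so differences of dim probe sets are understated. The authors' scaling was kept because the log2 medians of the arrays differed by less than 0.5. Of 22690 probe sets, 64 control probe sets were left out, and the 60% of the others with the highest mean log2 value were kept, which left 13576. Genes were named from the platform annotation supplied with the series, in which 20380 of the 22626 other probe sets had 1 gene symbol, 691 had several and 1555 had none. Through Entrez identifiers 20351 of them matched a current gene record, and 0 symbols needed an update. Probe sets with several symbols or none stayed in the tests but were given no name. No genome coordinates are printed, since no build is named with the values.

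Each kept probe set was tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend, two-sided, residual degrees of freedom 2, prior degrees of freedom 8.64), with Benjamini-Hochberg adjustment over all kept probe sets and a threshold of 0.05 on the adjusted p. Every difference is homozygous minus heterozygous. Gene lists were tested with limma's camera (two-sided, preset inter-gene correlation 0.01, Benjamini-Hochberg over 31 lists) on the probe set with the highest mean value of each gene. A list needed 5 measured members, and all 31 had them. The lists, the tests, the groups and the alternatives were fixed before the data were examined. They cover compartments and signalling pathways of the follicle, and markers of other cell types that a captured follicle could bring along.

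Genes were named by a fixed rule. It takes Hr, then up to 12 genes per direction past the threshold with the largest change. If fewer than 12 pass in all, it also takes the 10 genes per direction with the smallest unadjusted p whose samples do not overlap between the groups. From each list it takes up to 4 members with the smallest unadjusted p. A gene with several probe sets is represented by the brightest one. Xist, the Y-linked genes, the genes singled out when a sample was left out or as low in a single sample, Sparc, Mitf, and Sox10 as a melanocyte marker fall outside this rule and were chosen after their values were seen.

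The gene test was tested on simulated data made from the means and spread of the 13576 probe sets in this comparison, with 200 probe sets changed in each of 20 simulations. Of these, 50 each were changed 2-fold, 4-fold, 8-fold and 16-fold. The test recovered 8.90% of probe sets changed 2-fold, 78.4% of those changed 4-fold and 99.3% of those changed 8-fold, with a mean of 13.1 false calls per simulation. The large changes ease the adjusted threshold for the smaller ones. These shares therefore do not carry over to data without such large changes. In the data the probe set with the smallest p differed 6.71-fold and was not called. The list test was tested on simulated independent genes. With the preset correlation a shift of 0.70 (log2) in the hair shaft keratins was called in 20 of 20 simulations, and with a correlation estimated from the residuals it was called in 0 of 20. For independent genes at 2 residual degrees of freedom, losing a call with an estimated correlation therefore says little. In the data the estimated correlation was 0.11 for hair shaft keratins, 0.03 for fibroblast, 0.28 for melanocyte and 0.14 for adipocyte markers. Correlated genes and the fry test were not simulated, so the simulation does not show that calls with the preset correlation hold.

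The alternatives were quantile normalization, centring on the median, no filter, a filter keeping the upper 40%, pseudocounts of 1 and 128, eBayes without the trend or with robust estimation, the mean of a gene's probe sets, a threshold of 0.1, leaving out each sample in turn, the strain-field grouping, camera with an estimated correlation, fry, and the probe set with the largest variance for each gene. Robust estimation, the mean of a gene's probe sets and the threshold of 0.1 were planned for the counts of probe sets only. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.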

Results

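The Hos:HR-1 mouse is a hairless strain with a recessive mutation of Hr, a gene that encodes a nuclear corepressor needed for hair follicle cycling. Follicles of dorsal skin were profiled at day 14 after birth in 2 homozygous samples (replicates 2 and 3) and 2 heterozygous control samples (replicates 3 and 4) of the same N1 generation, all labelled male. The comparison asks which transcripts differ between follicles of the 2 genotypes, in a study of how the hair is lost. The median probe set intensity was 47.3 and 49.0 in heterozygous replicates 3 and 4, and 43.5 and 52.6 in homozygous replicates 2 and 3.

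Hr itself was measured by 2 probe sets whose differences had opposite signs. The brighter one read 293.5 and 80.9 in heterozygous replicates 3 and 4 and 90.1 and 156.8 in homozygous replicates 2 and 3, a log2 difference of -0.34 ± 0.52 (SE, n = 2 per group). The dimmer one read 46.1 and 45.4 against 64.9 and 49.4, a log2 difference of 0.19 ± 0.36. The labels do not say where the mutation lies in the transcript, so these levels do not check the genotype labels.

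Hair shaft keratins, the structural proteins of the hair fibre, were higher as a group in homozygous follicles, and markers of dermal fibroblasts and their matrix were lower as a group. All 12 measured hair shaft keratins lay above 0, with a median log2 difference of 0.66 (1.58-fold; SD over genes 0.39) and a camera adjusted p of 2.05e-05. Of 29 fibroblast and matrix genes 25 lay below 0, with a median of -0.49 (SD over genes 0.46) and a camera adjusted p of 3.87e-06. With an estimated correlation both lists had an adjusted p = 0.767, and with fry an adjusted p = 0.474. Neither list held a gene that passed over all probe sets or when adjusted over the list alone (0 of 12 and 0 of 29), so the values of single members below are not tested changes.

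Among the keratins, Krt83 read 642 and 912 in the heterozygous samples and 2124 and 1873 in the homozygous samples, a log2 difference of 1.35 ± 0.45 (SE, n = 2 per group). Krt33a differed by 1.07 ± 0.50, Krt35 by 1.05 ± 0.46 and Krt31 by 0.81 ± 0.40. In 6 of the 12 keratins both homozygous samples lay above both heterozygous samples. The keratin list also had a camera adjusted p under the threshold when any one sample was left out, with medians from 0.37 to 0.82, and lost it with homozygous replicate 3 grouped by its strain field (median 0.28, adjusted p = 0.621).

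Among the fibroblast genes, Dpt, which encodes the matrix protein dermatopontin, read 440.2 and 755 in the heterozygous samples and 149 and 148 in the homozygous samples, a log2 difference of -1.76 ± 0.46. Postn, encoding the matrix protein periostin, differed by -1.30 ± 0.52, Vim, the intermediate filament of mesenchymal cells, by -1.19 ± 0.53, and the fibrillar collagen gene Col3a1 by -0.85 ± 0.39. In 11 of the 29 genes both homozygous samples lay below both heterozygous samples. Sparc, encoding another matrix protein, had the largest difference in the opposite direction, 0.47 ± 0.80. Without heterozygous replicate 3 the camera call was lost (median -0.47, adjusted p = 0.0851), and by the strain field the median was -0.16 (adjusted p = 0.491).

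**Figure D1:**
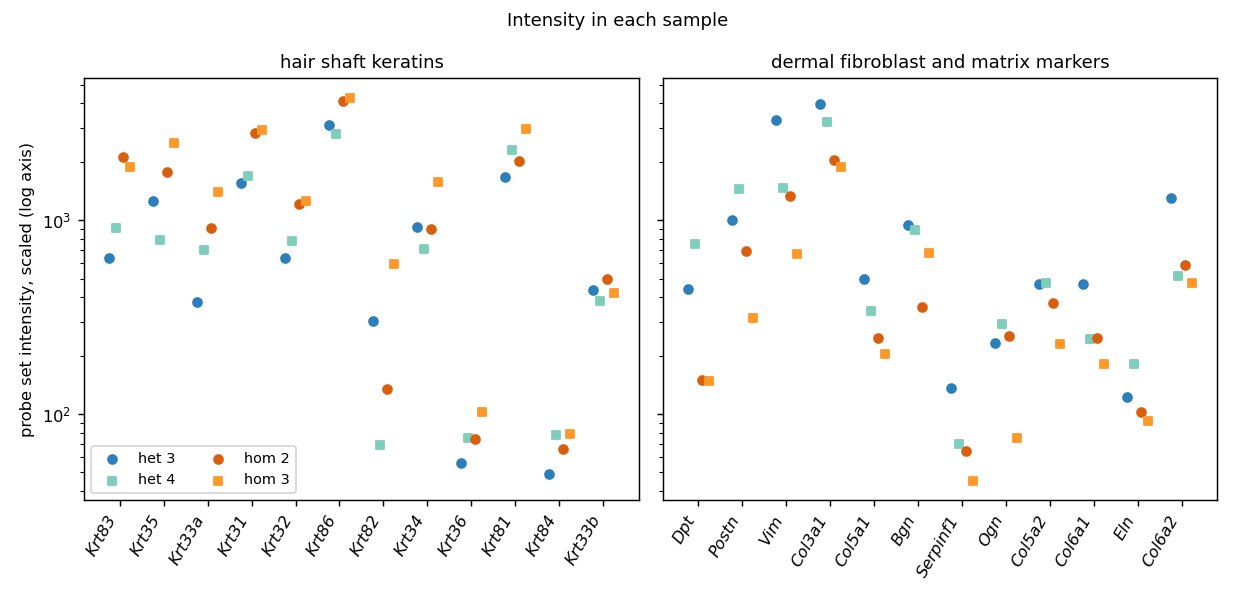
Probe set intensity (log axis) of the 12 hair shaft keratins and of the 12 dermal fibroblast and matrix genes with the smallest unadjusted p, 1 point per sample, with blue and green for heterozygous (het) replicates 3 and 4 and dark and light orange for homozygous (hom) replicates 2 and 3. Both homozygous points of Krt83 (2124 and 1873) lie above both heterozygous points (642 and 912), and both of Dpt (149 and 148) lie below (440.2 and 755).

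Pigment cell genes were also called higher as a group and adipocyte genes lower, with samples that stood less clearly apart. Of 11 melanocyte markers 10 lay above 0, with a median log2 difference of 0.41 (SD over genes 0.61; camera adjusted p = 0.0300; adjusted p = 0.795 with an estimated correlation; adjusted p = 0.827 with fry). Pmel, which encodes the protein of the melanosome fibrils, read 312 and 182 in the heterozygous samples and 678 and 1301 in the homozygous samples, a log2 difference of 1.84 ± 0.51 (SE, n = 2 per group). It was the 1 member that passed when adjusted over the list alone (limma adjusted p = 0.0468); 0 passed over all probe sets. The pigment enzyme genes Tyrp1 and Dct differed by 0.97 ± 0.59 and 0.79 ± 0.52, and Sox10, a transcription factor of the melanocyte and Schwann cell lineages, by -0.40 ± 0.37. The call was lost without homozygous replicate 3 (median 0.01, adjusted p = 0.670), without heterozygous replicate 3 (0.45, adjusted p = 0.615) and with no filter (0.30, adjusted p = 0.0651), and the median turned to -0.13 by the strain field. In 3 of the 11 genes both homozygous samples lay above both heterozygous samples and in 1 below. Relative to the mean of all samples the list median was -0.58 and 0.34 in heterozygous replicates 3 and 4 and -0.10 and 0.43 in homozygous replicates 2 and 3. Heterozygous replicate 4 thus lay above homozygous replicate 2.

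Of 12 adipocyte markers 11 lay below 0, with a median log2 difference of -0.23 (SD over genes 0.44; camera adjusted p = 0.0313; adjusted p = 0.767 with an estimated correlation; adjusted p = 0.546 with fry). Car3, a carbonic anhydrase abundant in fat and muscle, read 3959.8 and 3323 in the heterozygous samples and 1324 and 1390.4 in the homozygous samples, a log2 difference of -1.40 ± 0.40. Relative to the mean of all samples the list median was 0.37 and 0.08 in heterozygous replicates 3 and 4 and 0.05 and -0.36 in homozygous replicates 2 and 3. In 3 of the 12 genes both homozygous samples lay below both heterozygous samples and in 1 above. The adipokine gene Adipoq differed by -0.82 ± 0.44, the lipoprotein lipase gene Lpl by -0.64 ± 0.45 and the lipid droplet gene Plin4 by -0.46 ± 0.40. No member passed over all probe sets or when adjusted over the list alone (0 of 12). The call was lost without homozygous replicate 3 (median -0.06, adjusted p = 0.588), without heterozygous replicate 3 (-0.17, adjusted p = 0.615) and by the strain field (0.07, adjusted p = 0.914).

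The spike-ins moved with the genotypes, and so with the sample medians of the keratin, fibroblast and adipocyte lists. The melanocyte medians did not part the groups. The 9 hybridization spike-ins were lower in both homozygous samples for 9 of 9 probe sets, by a mean log2 difference of -1.04 (2.06-fold higher in heterozygous samples). The ratio of the 3' to the middle Gapdh probe set, which grows as transcripts shorten, was 17.2 and 30.1 in heterozygous replicates 3 and 4 and 15.4 and 14.8 in homozygous replicates 2 and 3. The same ratio for Actb was 42.1 and 11.3 against 45.9 and 33.7, so it did not part the groups. The 5' probe sets of both genes mostly lay below the median of their array and are not used here.

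**Figure D2:**
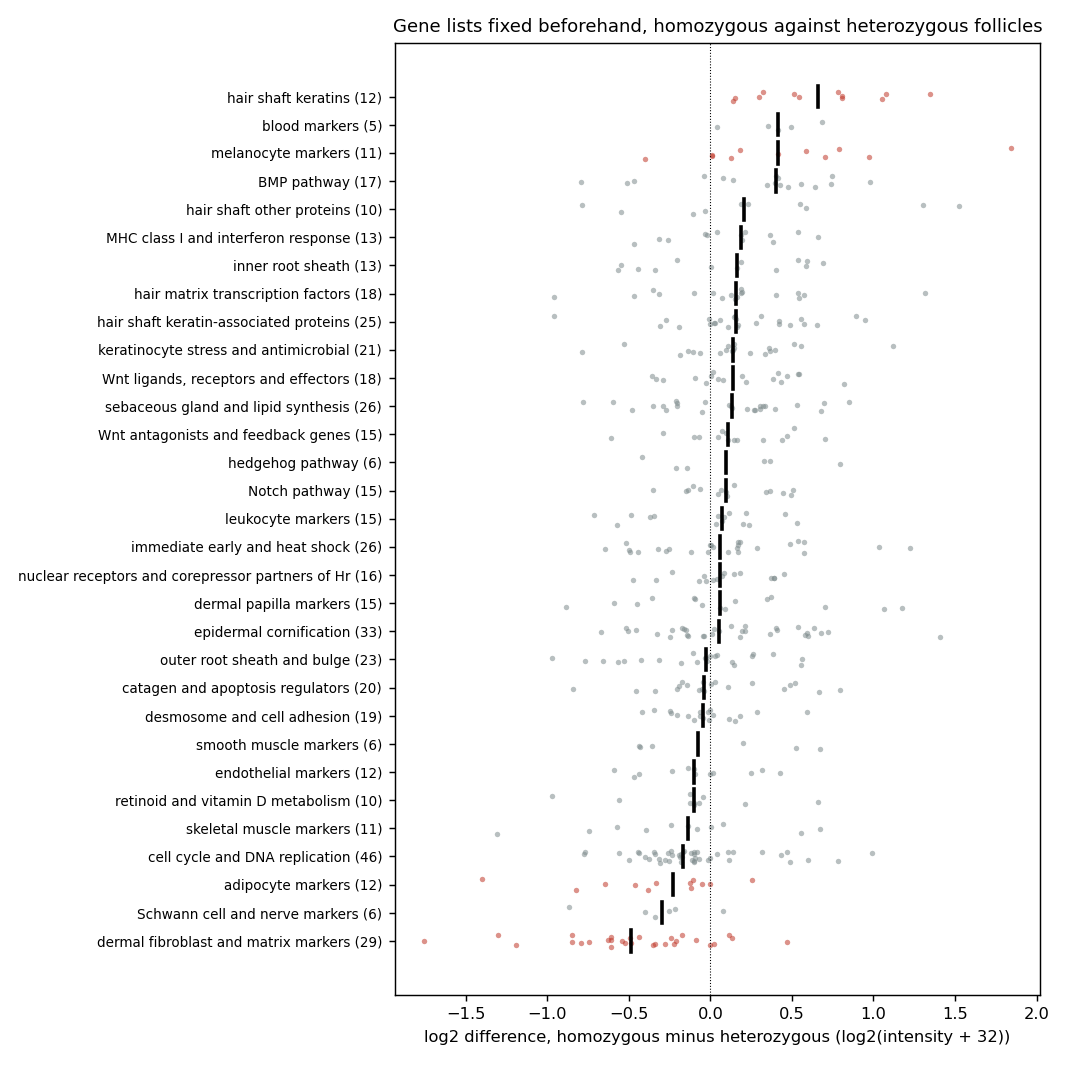
Difference between homozygous and heterozygous follicles on the log2(intensity + 32) scale for each measured member (points) and the median (bars) of 31 gene lists, with the number of members in brackets and lists with a camera adjusted p under 0.05 in red. The medians run from 0.66 for the hair shaft keratins to -0.49 for the dermal fibroblast and matrix markers.

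The other genes of the hair shaft and the matrix that feeds it did not pass as lists. Gprc5d, an orphan receptor gene of the hair cortex, read 105 and 143 in the heterozygous samples and 348 and 492 in the homozygous samples (log2 difference 1.53 ± 0.43, SE, n = 2 per group), and S100a3, a calcium-binding protein of the hair cuticle, read 1074 and 1162 against 3423.5 and 2299. These are members of the 10 other hair shaft proteins (median 0.21, camera adjusted p = 0.167), in which 1 gene, Gprc5d, passed when adjusted over the list alone (limma adjusted p = 0.0485) and 0 passed over all probe sets. The 25 keratin-associated proteins, which cross-link the keratin filaments, had a median of 0.16 (camera adjusted p = 0.173). Of these 19 lay above 0, with Krtap19-3 at 0.89 ± 0.37, and 6 below, with Krtap4-2 at -0.96 ± 0.46. Foxn1, the transcription factor mutated in nude mice, was dim, at 3.5 and 16.1 against 65.9 and 76.2 (1.32 ± 0.39). Bnc1, encoding the zinc finger protein basonuclin, differed by -0.96 ± 0.46. Both belong to the 18 hair matrix transcription factors (median 0.16, camera adjusted p = 0.468).

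Lists of the root sheaths and of neighbouring compartments did not pass. The 13 inner root sheath genes had a median log2 difference of 0.16 (8 above 0; camera adjusted p = 0.783), with the sheath keratin Krt72 at 0.69 ± 0.45 and the transglutaminase gene Tgm3 at -0.57 ± 0.35. The 23 genes of the outer root sheath and bulge had a median of -0.03 (9 above 0; camera adjusted p = 0.468), with Nfatc1, a regulator of bulge stem cells, at -0.77 ± 0.38 and Gas1 at -0.97 ± 0.51, though another probe set of Gas1 read 0.22. The 15 dermal papilla markers had a median of 0.06 (8 above 0; camera adjusted p = 0.7003), with the leptin receptor gene Lepr at 1.17 ± 0.40, the protease gene Corin at 1.06 ± 0.48 and the proteoglycan gene Vcan at -0.88 ± 0.42. The 33 epidermal cornification genes had a median of 0.06 (19 above 0; camera adjusted p = 0.468), with the protease inhibitor gene Cst6 at 1.41 ± 0.56. The 26 genes of the sebaceous gland and lipid synthesis had a median of 0.13 (camera adjusted p = 0.7003), with the fatty acid synthase gene Fasn at 0.70 ± 0.46. The 19 genes of desmosomes and cell adhesion had a median of -0.04 (camera adjusted p = 0.703).

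Among the signalling lists, the 17 BMP pathway genes came nearest to the threshold. Of these 13 lay above 0, with a median log2 difference of 0.40 and a camera adjusted p of 0.0565. Bambi, encoding a BMP and TGF-beta pseudoreceptor, read 501 and 395 in the heterozygous samples and 890 and 923 in the homozygous samples (0.98 ± 0.45, SE, n = 2 per group). The inhibitory Smad7 differed by 0.75 ± 0.40, and the receptor gene Bmpr2 by -0.79 ± 0.46. The 18 Wnt ligands, receptors and effectors had a median of 0.14 (camera adjusted p = 0.372) and the 15 Wnt antagonists and feedback genes 0.11 (camera adjusted p = 0.468), with the secreted antagonists Sfrp2 at -0.61 ± 0.36 and Wif1 at 0.70 ± 0.46. Medians were 0.09 for the 6 hedgehog pathway genes (camera adjusted p = 0.7003), 0.09 for the 15 Notch pathway genes (camera adjusted p = 0.548) and 0.06 for the 16 nuclear receptors and corepressor partners of Hr (camera adjusted p = 0.714). The 10 genes of retinoid and vitamin D metabolism had a median of -0.10 (camera adjusted p = 0.548), with Rarres2, which encodes chemerin, at -0.97 ± 0.45.

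Genes of growth, regression and stress also gave no list call. The 46 genes of the cell cycle and DNA replication had a median log2 difference of -0.17 (35 below 0; camera adjusted p = 0.319), although Gmnn, the inhibitor of replication licensing, read 723 and 728 against 1565 and 1388 (0.99 ± 0.44). The 20 catagen and apoptosis regulators had a median of -0.04 and a mean of 0.04, and camera pointed up (adjusted p = 0.910), with the growth factor receptor gene Fgfr1 at -0.84 ± 0.37 and Bcl2, an inhibitor of apoptosis, at 0.79 ± 0.38. The 26 immediate early and heat shock genes had a median of 0.06 (camera adjusted p = 0.765), with the chaperone gene Hspa8 at -0.50 ± 0.22 and the immediate early gene Ier3 at 1.22 ± 0.56. Medians were 0.14 for the 21 keratinocyte stress and antimicrobial genes (camera adjusted p = 0.468) and 0.19 for the 13 genes of MHC class I and the interferon response (camera adjusted p = 0.548).

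Apart from the fibroblast, adipocyte and melanocyte markers above, markers of other cell types that could be captured with a follicle did not pass as lists. The 6 Schwann cell and nerve markers had a median log2 difference of -0.29 (5 below 0; camera adjusted p = 0.167), with the myelin gene Pmp22 at -0.87 ± 0.45, and the 5 blood markers had a median of 0.42 (5 above 0; camera adjusted p = 0.167). The 12 endothelial markers had a median of -0.10 (camera adjusted p = 0.548) and the 11 skeletal muscle markers -0.14 (camera adjusted p = 0.466). The 15 leukocyte markers had a median of 0.07 while their mean was -0.03 and camera pointed down (adjusted p = 0.703). The 6 smooth muscle markers had a median of -0.08 while their mean was 0.03 and camera pointed up (adjusted p = 0.809). Apart from Pmel and Gprc5d, 0 members of any of the 31 lists passed when adjusted over the list alone, and 0 passed over all probe sets. Adjusting over a list alone does not correct for the number of lists. Both passes lay just under 0.05, and as many could come by chance over 31 lists. With an estimated correlation 0 of the 31 lists passed.

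Of single probe sets, limma called 0 of 13576 at an adjusted p under 0.05, with a smallest unadjusted p of 2.90e-04. At an unadjusted p under 0.05 there were 312 (172 higher and 140 lower in homozygous follicles), where chance alone would give 679. Robust eBayes and a test per gene on the mean of its probe sets also called 0, with 290 and 264 at an unadjusted p under 0.05. The median 95% interval, not adjusted for the number of tests, reached 0.93 (log2) to either side, or 1.90-fold. Differences of that size or smaller were therefore mostly not detectable with these arrays, and larger ones also went uncalled. The smallest p belonged to a probe set without a single gene symbol. It read 1879 and 4018 in the heterozygous samples and 292 and 497 in the homozygous samples (log2 difference -2.75 ± 0.52, SE). Another such probe set read 403 and 748 against 3081 and 2088 (2.14 ± 0.48). Both homozygous samples lay above both heterozygous samples in 1846 probe sets and below both in 1812, together 26.9%, where chance gives 33.3%.

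Of named genes, those with the smallest unadjusted p among genes whose samples did not overlap did not pass. Higher in both homozygous samples were Creld1 (1.81 ± 0.40, log2 ± SE, n = 2 per group), the autophagy gene Ambra1 (1.59 ± 0.38), Mospd1, the kinase gene Map3k4, Mettl7a1, the peptidase gene Prep, Gpnmb, which encodes a melanosomal glycoprotein, and Cdk5rap3, besides Pmel and Gprc5d. Creld1 read 10.3 and 4.7 against 78.4 and 140.1. Lower in both were Vat1 (-1.78 ± 0.37), the dynamin gene Dnm1 (-1.71 ± 0.38), the phosphatase gene Ptprd, the p53 regulator Mdm4, Ago2, which encodes an Argonaute protein, Coq10a, Tnks1bp1 and 1500002F19Rik, besides Dpt and Car3. The lower group had a mean intensity under the pseudocount of 32, near the bottom of the scale, for Creld1, Ambra1, Mospd1, Map3k4, Vat1, Dnm1, Mdm4, Ago2, Coq10a, Tnks1bp1 and 1500002F19Rik, and among the list members named above for Foxn1, Lepr, Bcl2, Fgfr1, Nfatc1 and Bmpr2. Other kept probe sets of Mettl7a1 (-0.00) and Coq10a (0.17) had the opposite sign to the named one. Of the other 2 of Ptprd, 1 had the opposite sign (0.36) and 1 the same sign (-0.42).

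The heterozygous samples resembled each other less than samples of different genotypes did, and the homozygous samples about as much as the closest of those. Across probe sets the correlation of log2 values was lowest between the 2 heterozygous samples (r = 0.884), against 0.929 between the 2 homozygous samples and 0.906 to 0.931 between genotypes. The SD of the log2 differences was 0.77 for the heterozygous pair, 0.595 for the homozygous pair and 0.597 to 0.685 between genotypes; genes are not independent replicates, so no p-value is given. The first principal component (47.9% of the variance) set heterozygous replicates 3 and 4 farthest apart, and the component that parted the genotypes was the third (24.0%).

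Heterozygous replicate 4 differed from the other samples in transcripts of the sex chromosomes. Xist, the RNA that silences an X chromosome in female cells, read 6996 there and 68.8 in heterozygous replicate 3, 85.6 in homozygous replicate 2 and 71.4 in homozygous replicate 3. The Y-linked Eif2s3y read 11.2 there and 343, 516 and 421 in the other samples, and the Y-linked Kdm5d read 18.8 there and 303, 147 and 105. Dimmer probe sets of the Y-linked genes, left out by the filter, did not single this sample out (Uty read 25.2 there and 26.2, 5.9 and 21.8 in the others). All 4 samples are labelled male, so the transcript pattern of heterozygous replicate 4 differs from its label. Without it, limma called 0 probe sets with 834 at an unadjusted p under 0.05, and camera called 5 lists: hair shaft keratins (median 0.50, adjusted p = 9.34e-04), melanocyte markers (0.76, adjusted p = 2.25e-05), fibroblast markers (-0.67, adjusted p = 6.06e-06), adipocyte markers (-0.43, adjusted p = 0.0213) and keratin-associated proteins (0.47, adjusted p = 9.34e-04). That fit leaves 1 heterozygous sample, assumed to vary like the homozygous ones.

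**Figure D3:**
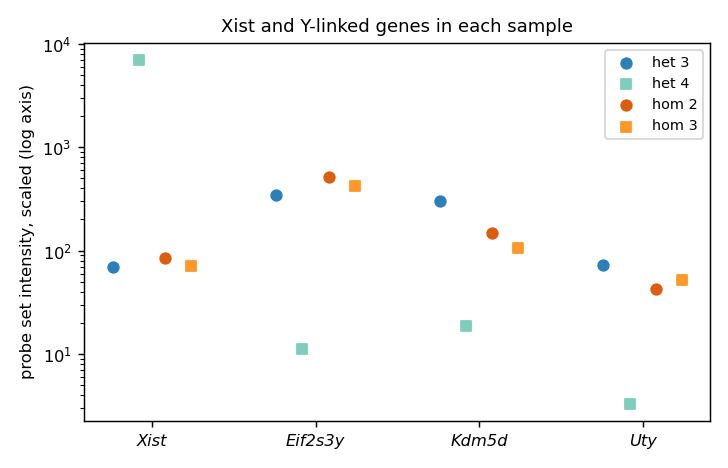
Probe set intensity (log axis) of Xist and of the Y-linked genes Eif2s3y, Kdm5d and Uty, 1 point per sample, with heterozygous (het) replicates 3 and 4 and homozygous (hom) replicates 2 and 3. In the brightest probe set of each gene, which is the one drawn, heterozygous replicate 4 alone has high Xist (6996) and low Eif2s3y (11.2), Kdm5d (18.8) and Uty (3.3).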

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

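All alternatives here were planned and none was added after the results were seen. Limma called 0 probe sets in the reported fit and under every alternative but 1: leaving out a sample gave 0 to 17, with the 17 found without heterozygous replicate 3, when the sample with high Xist is the only control; Xist, Eif2s3y, Myh1 and Nfkbia are among them. At an unadjusted p under 0.05 there were 312 probe sets, 743 with no filter (more probe sets tested), 165 with the stricter filter (fewer tested) and 271 to 1151 without 1 sample. Camera called 4 lists, 2 to 6 without 1 sample (2 without heterozygous replicate 3), and 0 by the strain field, with an estimated correlation or with fry. Without 1 sample the medians (log2) ran from 0.37 to 0.82 for hair shaft keratins (adjusted p from 3.16e-05 to 0.0348), from -0.67 to -0.37 for fibroblast markers (6.06e-06 to 0.0851), from 0.0121 to 0.76 for melanocyte markers (2.25e-05 to 0.670) and from -0.54 to -0.0614 for adipocyte markers (0.00514 to 0.615). By the strain field, with homozygous replicate 2 as the only homozygous sample, the medians were 0.28, -0.16, -0.13 (turned in sign) and 0.0676. For the last, camera still pointed down. An estimated correlation and fry leave the medians at 0.66, -0.49, 0.41 and -0.23; the simulated list of independent genes also lost its call with an estimated correlation. With no filter the melanocyte median was 0.30 (adjusted p = 0.0651), and the cause was not tested, nor for the losses by sample or strain field. The other scalings, filters, pseudocounts and variance settings left these 4 lists called, but the pseudocount moved medians by over 1.5 times: melanocyte 0.72 with the smaller and 0.18 with the larger, adipocyte -0.37 and -0.15, fibroblast -0.31 with the larger; the stricter filter gave adipocyte -0.38. Of 27 lists not called, 3 passed in 9 of 397 values: the BMP pathway with median centring (0.38), the stricter filter, the larger pseudocount (0.20), the largest-variance probe set or without homozygous replicate 2, keratin-associated proteins without homozygous replicate 2 or heterozygous replicate 4, and skeletal muscle markers without homozygous replicate 3 or heterozygous replicate 3. Of 135 named genes 15 changed sign by the strain field and 0 with another scaling or pseudocount (129 had a value at the smaller pseudocount), and of the 126 to 133 with a value 4, 4, 5 and 7 did without homozygous replicate 2, homozygous replicate 3, heterozygous replicate 3 and heterozygous replicate 4. No paired analysis was possible because the groups share only replicate number 3. Dim probe sets limit the rest: the dimmest kept had a mean near intensity 30.4, close to the pseudocount of 32.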

Other observations

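The tests here of the intensity trend, of captured dermis (on fibroblast markers and on keratins), of differences between animals, of sex and of lost transcripts were chosen only after the result was seen. The tests of the label conflict and of captured stretches of follicle were chosen before, but how their values were read was settled after they were seen. By the readings written before, an r without a clear positive value in both pairings of samples given below stood for a mislabelled sample. A list outside the central 95% of random lists by over 1.3-fold stood for other captured stretches. Both were met, and the stricter readings set afterwards leave both explanations open.

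Of the 31 lists, 2 set the heterozygous samples apart by more than the central 95% of random lists, where 1.55 were to come by chance. Keratin-associated proteins were 1.48-fold higher by median in heterozygous replicate 4 than in replicate 3 (21 of 25 genes higher), at percentile 99.98 of 10000 random lists matched on brightness, with Krtap15 at 3028 against 1109. Melanocyte markers were 1.60-fold higher by median in replicate 4 (8 of 11 genes higher, percentile 99.57), with Tyrp1 at 1994 against 572 and Mitf at 972 against 236. The other hair shaft lists lay inside the random range, with the 12 keratins at percentile 78.55 and the 10 other hair shaft proteins at 79.33, and each side is 1 sample.

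The first pattern weighed is that hair shaft keratins were higher and fibroblast markers lower in homozygous follicles. The tables argue against an intensity trend between arrays as the cause, since after quantile normalization, which moved the brightest hundredth of probe sets from -0.28 to 5.34e-05, the medians were 0.691 for the keratins and -0.48 for the fibroblast markers. A larger share of dermis around the heterozygous follicles stays open for the fibroblast markers: markers of other dermal cell types over intensity 100 had a median of -0.377 (18 of 22 below 0, 95% bootstrap interval -0.44 to -0.22), and without the 8 adipocyte genes among them it was -0.36 (10 of 14 below 0) with an interval that reached 0.07, while over all 51 members the median was -0.12 (-0.34 to 0.01). For the keratins the values argue against a larger share of dermis but do not exclude it. Root sheath genes, which a larger epithelial share would raise alike, had a median of -0.00465 (interval -0.18 to 0.15, against 0.31 to 0.93 for the keratins). These intervals are over genes and not over samples. The root sheath genes were not filtered by brightness, and differences of dim ones are understated. Differences between animals unrelated to genotype stay open, with 11 of 31 lists parting the samples by genotype (35.5%, chance 33.3%) 4 lists called against 3 for the highest other split of the 4 samples, but 0 probe sets called against 8 and 312 at an unadjusted p under 0.05 against 767 and 948; 3 splits are too few for a share under 0.05, and an effect of the genotype stays open beside it, as does the difference in spike-ins, which cannot be separated from the groups here.

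The second pattern is that the 2 heterozygous samples differed more than any other pair. An animal of the other sex in place of heterozygous replicate 4 is a candidate explanation for a part of it whose size was not tested. Xist was 81.7 times the highest of the other samples, and the 2 bright Y-linked genes were at least 5.59 times higher in each other sample. These few genes do not explain a lower correlation over all probe sets. Sex alone would set heterozygous replicate 4 as far from the homozygous samples, yet r was 0.919 and 0.906 there, against 0.884 for the heterozygous pair. Transcripts lost in amplification may add to the difference of the heterozygous pair. In heterozygous replicate 4 alone, 21 probe sets were under 20 and over 100 in the other 3 samples. Snx6 and Zfp148 but also the Y-linked Eif2s3y and Kdm5d were among them. The counts were 5, 3 and 0 for heterozygous replicate 3, homozygous replicate 2 and homozygous replicate 3. Whether other stretches of follicle or other cells were captured cannot be told apart from chance by the number of lists, 2 of 31 outside the central 95% of random lists where 1.55 were to come by chance. That number does not weigh how far a list lay outside, and the keratin-associated proteins were at percentile 99.98. Random lists draw each gene independently, so they are too narrow a measure for genes of a family that vary together. The explanation stays open.

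The third pattern is the strain field of homozygous replicate 3, which reads heterozygous. If the sample is homozygous, its differences from one heterozygous sample could go with those of homozygous replicate 2 from the other, but across probe sets these had r = -0.219 and -0.16 in the 2 possible pairings. The pairing that ignores genotype, of the heterozygous pair with the homozygous pair, had r = -0.06. A mislabelled sample and a genotype effect that is weak beside the spread between samples would both leave r without a clear positive value. The 2 therefore cannot be told apart here. The sign of r follows from the SDs of the differences between samples. It falls below 0 when the same-genotype pairs differ more than the 2 other pairs of different genotypes. That SD was 0.77 for the heterozygous pair, 0.595 for the homozygous pair and 0.597 to 0.685 between genotypes. A negative r thus came mostly from the distance between the heterozygous samples, and it says little about the label of homozygous replicate 3.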
